A study of Ambystoma mexicanum with 6 samples.

How the data were processed

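The study measured RNA of whole retinas of the axolotl (Ambystoma mexicanum), a salamander that regrows its retina after surgical removal (retinectomy). Per the labels' protocols, 12 adult leucistic (pale-skinned) animals were used, retinas were pooled by 4 into 3 uninjured samples, and retinas that had regrown for 27 days in the same animals were pooled into 3 samples made up of the same animals. RNA was extracted from frozen tissue at a sequencing provider and made into libraries with a NEBNext Ultra II RNA kit, per the labels' protocols. The strand setting, the genome build and the annotation are not given in the sources used here.

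The submitters' processing notes name Trimmomatic 0.38, a read trimmer, and Salmon 0.13.1, which estimates how many reads each transcript received. Per the file headers, the deposited file of each sample gives for every gene an estimated count of reads, a TPM value (transcript abundance, scaled by the authors for gene length and to the same total in each library) and the gene's length. Between 30.7% and 34.2% of the deposited estimated counts were not whole numbers. The deposited table of the whole series is named a count table, but its values are not reads per gene. In each library, 100% of the values of genes above 1 TPM equalled TPM multiplied by that library's total of estimated reads in M (1000 times 1000 reads), within a tolerance of 1%. Such values carry no weight for gene length, so the estimated counts of the sample files, rounded to whole numbers, were tested, and the series table was used only as an alternative. Salmon divides reads between similar transcripts, so values of near-identical gene copies and of overlapping genes are uncertain.

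The files name 99088 genes by identifiers that begin with AMEX60DD and hold no gene symbols. None (0) of these identifiers matched the RefSeq gene table of assembly UKY_AmexF1_1. No gene could therefore be named, and the 30 lists of retinal cell types, pathways and neighbouring tissues fixed before the data were examined could not be tested. The rule for genes to name had the same limit. Its second part was applied without the demand for a symbol, to 2 genes in each direction. These had the largest fitted changes among the 9416 genes past the threshold with a mean of at least 5 CPM (reads per M reads of the library) and the same direction in all 3 same-numbered pairs. The 15 most abundant genes are described by their rank. The groupings of genes by size of change, abundance, length and identifier type were chosen after seeing the data.

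The only comparison of the labels, regenerating against uninjured, was made with edgeR 4.0.16 in R 4.3.3. Genes with too few reads were removed with filterByExpr at its minimum count of 10, libraries were scaled with TMM, and the robust quasi-likelihood F-test was applied to all 6 libraries without a block. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. A standard error (SE) was taken as the log2 fold change divided by the square root of F. Values per group are TMM-scaled CPM with SD over 3 pools. The level of a gene with no read in a group was bounded at 3 reads per library. Intervals of shares are 95% Wilson intervals; intervals and floors cover counting error only. For measures with 1 value per library, an exact two-sided permutation test of 3 against 3 cannot go below p = 0.10. Labels describe each library as a pool of 4 animals, so the spread between libraries is that between pools.

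Same-numbered pools came from the same animals, per the labels, so the replicate number was tried as a block. Over genes, the deviations of same-numbered pools from their group means had correlations between -0.01 and 0.07. Within groups, libraries differed by at least 13.5 times the variance that read sampling alone gives, so no pair of files held the same reads within sampling noise. Depth was 29.4 to 37.4 M estimated reads per library, at which 3 reads correspond to 0.0753 to 0.109 TMM-scaled CPM.

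The test was checked on simulated counts for 37844 genes drawn from the real means, dispersions and library sizes, with 200 genes changed, 50 at each size. It recovered 0% of the 2-fold, 18% of the 4-fold, 58% of the 8-fold and 76% of the 16-fold changes, with 0 calls in the wrong direction. Of 88 calls 12 were false, a larger share than the threshold of 0.05 sets. In the data 41.6% of the tested genes were called, far more than the 200 changed here. The adjusted p was therefore harder to pass in the simulation, and the recovered shares do not carry over to the data. A limma 3.58.1 test of log2 transcript length recovered 79.5% of 200 shifts of 0.5 among 12691 genes, with 13 false calls. Alternatives were other scalings, filters, thresholds and tools (DESeq2 1.42.0, limma-voom, limma on log2(TPM + 0.5) for genes with a mean of at least 0.5 TPM, where a fold change is on that shifted scale), offsets for effective length, the block, the series table, and leaving out each library.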

Results

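RNA of 6 retina pools was profiled, 3 from uninjured axolotl eyes and 3 from eyes whose retina had been removed and had regrown for 27 days. Each pool held 4 retinas, and pools with the same number came from the same animals. The uninjured libraries held 35.7, 37.4 and 31.0 M estimated reads and the regenerating ones 29.4, 32.0 and 34.2 M. The design poses a single question, namely how far the transcriptome of the regrowing retina differs from that of the uninjured retina. Genes carry only identifiers in the files, so they are described by abundance, length and direction, and by identifier for a few.

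The 2 groups differed across much of the transcriptome. The first principal component of log2 CPM held 79.0% of the variance and placed the regenerating pools between 185 and 196 and the uninjured pools between -221 and -129. The regenerating pools lay close together, with Pearson correlations of log2 CPM across genes of 0.95 to 0.97. Uninjured pools 2 and 3 correlated at 0.98, whereas uninjured pool 1 correlated with them at 0.91 and 0.92 and stood apart on the second component, which held 9.15% of the variance. Pool 1 also correlated with the regenerating pools at 0.77 to 0.78, against 0.69 to 0.71 for pools 2 and 3. These correlations are across genes, which are not independent replicates.

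**Figure D1:**
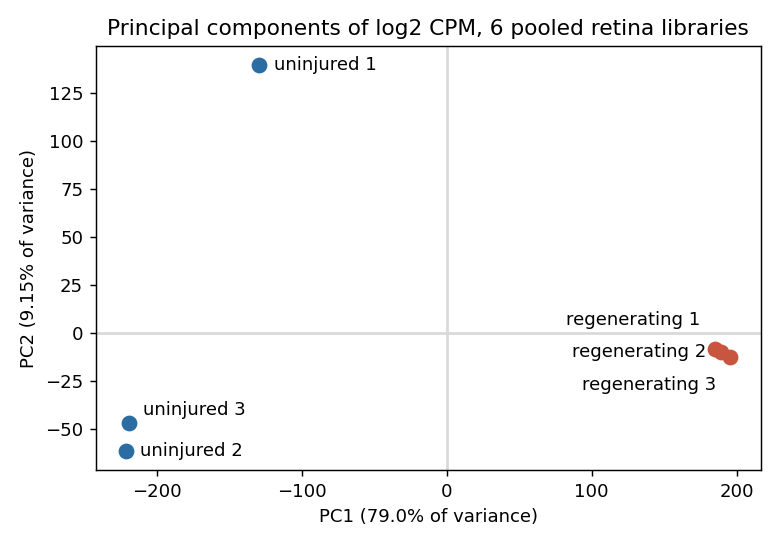
Scores of the 6 libraries on the first (x, 79.0% of variance) and second (y, 9.15%) principal components of log2 CPM, blue for uninjured and red for regenerating pools, 1 point per library. The regenerating pools sit together at 185 to 196 on the first component, and uninjured pool 1 lies apart from pools 2 and 3.

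Fewer genes were detected in the regenerating retina. At least 1 read was found for 64698 ± 375 genes (SD, n = 3) in uninjured and 61808 ± 814 (SD, n = 3) in regenerating libraries. After thinning every library to 29.4 M reads the numbers were 63525 ± 643 and 61268 ± 539 (SD, n = 3 each). Both differences exceeded the spread between pools, and the exact two-sided permutation test gave p = 0.10, the smallest it allows with n = 3 per group. Of the genes read in 1 group alone, 181 had no read in any regenerating library and at least 10 in every uninjured library. Another 73 had no read in any uninjured library and at least 10 in every regenerating library. The other 9 ways of splitting the 6 libraries gave at most 12 such genes in both directions together, against 254. Each of those splits holds libraries of both groups on both sides, so these 254 genes cannot count there. The 12 are thus no chance level for the 254. Their median TMM-scaled level where they were read was 0.794 CPM in the uninjured and 1.07 CPM in the regenerating pools. No read in a library allows a level of up to 0.0753 to 0.109 CPM on that scale.

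Of 37844 genes tested, 7729 were higher and 8004 lower in regenerating than in uninjured retinas (edgeR quasi-likelihood test, adjusted p under 0.05), or 41.6% of the genes tested. The median change was 3.50-fold among the genes that rose and 3.86-fold among those that fell, with a median SE of 0.32 on the log2 scale. With the 72 genes that had no read in any uninjured library and the 167 with none in any regenerating library set at their bound, the medians were 3.50-fold and 3.85-fold. By fitted change, 2579 genes fell and 1927 rose by at least 8-fold, 1202 fell and 617 rose by at least 32-fold, and 426 fell and 209 rose by at least 128-fold. With genes that had no read in a group at their bound, the numbers were 2502 and 1914, 1054 and 559, and 285 and 142. Of the called genes, 99.9% moved in the same direction in all 3 same-numbered pairs of pools. They were called on the same libraries, so this share depends on the selection.

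The excess of falls at 8-fold turned without uninjured pool 1, where 3516 genes rose and 2942 fell by as much. At 32-fold 1174 then rose and 1359 fell, at 128-fold 390 rose and 506 fell, and 10009 genes were called higher and 9131 lower in all. Of all calls 49.1% were higher, against 39.7% with library totals and 34.6% with limma on log2(TPM + 0.5), settings that moved the median fold change of all shared genes by -0.16 and -0.26 on the log2 scale.

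**Figure D2:**
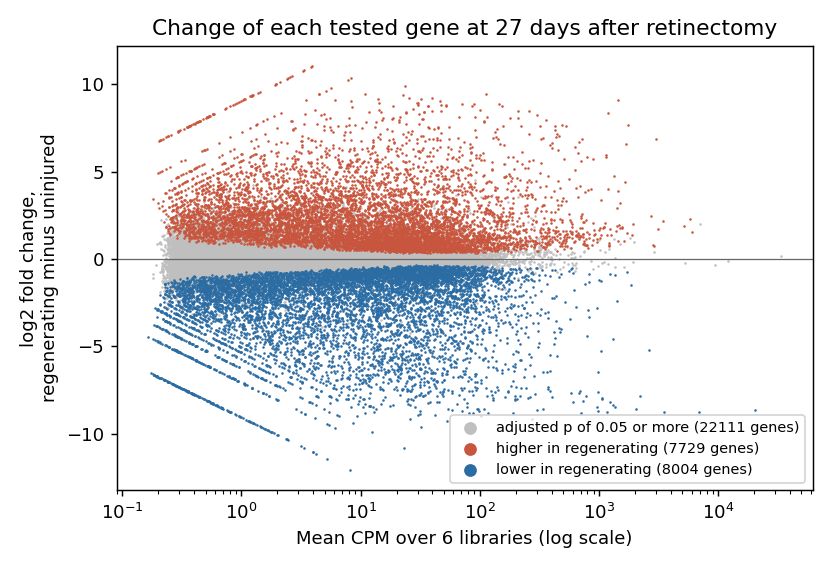
log2 fold change, regenerating minus uninjured (y), against the mean CPM over the 6 libraries (x, log scale), 1 point per gene of the 37844 tested. Red points are the 7729 genes called higher and blue points the 8004 called lower at an adjusted p under 0.05; the straight lines of points at the left edge are genes with few or no reads in 1 group.

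The genes that fell had made up a large part of the uninjured transcriptome. Genes called lower took 46.4% ± 7.99 of the reads (SD, n = 3) in uninjured and 8.71% ± 0.264 (SD, n = 3) in regenerating libraries. By pool, the uninjured shares were 37.2%, 51.1% and 51.0%. Genes called higher took 18.4% ± 4.92 and 56.0% ± 0.425 (SD, n = 3 each). The genes were selected on the same libraries, so the direction and size of these shares depend on the selection. The genes with a fitted fall of at least 128-fold alone took 13.0% ± 4.38 of uninjured reads (SD, n = 3) and 0.0378% ± 0.00649 of regenerating reads (SD, n = 3). In uninjured pool 1 their share was 7.94% (95% Wilson interval 7.94% to 7.95%), against 15.5% (15.5% to 15.5%) in each of pools 2 and 3. The genes that rose by at least 128-fold took 0.0117% ± 0.00138 of uninjured and 2.50% ± 0.242 of regenerating reads (SD, n = 3 each).

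Among the 15 genes with the highest mean CPM over all libraries, 3 fell, 6 rose and 6 did not pass the threshold. The 3 that fell held some of the highest levels in the uninjured retina. The gene ranked 2, 5562 bases long, went from 40362 ± 18552 CPM to 101 ± 8.28 CPM (SD, n = 3 each), a 398-fold fall. The gene ranked 6 went from 13771 ± 4173 to 32.4 ± 3.12 CPM, and that ranked 11 from 7055 ± 3257 to 16.7 ± 2.32 CPM (SD, n = 3 each). Their log2 changes were -8.64, -8.73 and -8.73, with SE of 0.58, 0.41 and 0.56 and edgeR adjusted p of 0.000117, 4.39e-05 and 9.87e-05.

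Of the 6 abundant genes that rose, 1 changed far more than the rest. The gene ranked 14 went from 51.0 ± 7.87 to 5977 ± 1281 CPM (SD, n = 3 each), a 117-fold rise with an edgeR adjusted p of 4.39e-05. The genes ranked 7, 8, 10, 12 and 13 rose by 2.88-fold to 4.89-fold. The gene ranked 7, which rose 2.88-fold at an edgeR adjusted p of 0.0171, no longer passed when uninjured pool 2 or 3 or regenerating pool 2 or 3 was left out, with adjusted p of 0.0687, 0.0602, 0.0535 and 0.0571. Over all alternatives its adjusted p was 8.44e-05 to 0.136, the highest in the edgeR test for a change of more than 2-fold, which the gene ranked 13 also missed at 0.0573 (range 1.61e-05 to 0.0573).

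The most abundant gene of all, AMEX60DD038502, differed by less than the spread between pools, at 31483 ± 4837 CPM in uninjured and 35778 ± 5674 CPM in regenerating pools (SD, n = 3 each; edgeR adjusted p = 0.640, range over alternatives 0.436 to 1.00). The gene ranked 5, AMEX60DD002298, measured 8160 CPM in uninjured pool 1 but 133 and 128 CPM in pools 2 and 3, and 4289, 17831 and 11439 CPM in the regenerating pools. Its change did not pass the threshold over all pools (edgeR adjusted p = 0.373) and did without uninjured pool 1 (adjusted p = 0.000665; range over alternatives 0.000665 to 0.711). Without that pool the genes ranked 4 and 15 passed as well, at adjusted p of 0.0426 (range 0.0426 to 1.00) and 0.0255 (range 0.0255 to 1.00), the latter also in DESeq2 at 0.0362 and in limma-voom at 0.0298. These 2 identifiers and the ranks were chosen after their values were seen.

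**Figure D3:**
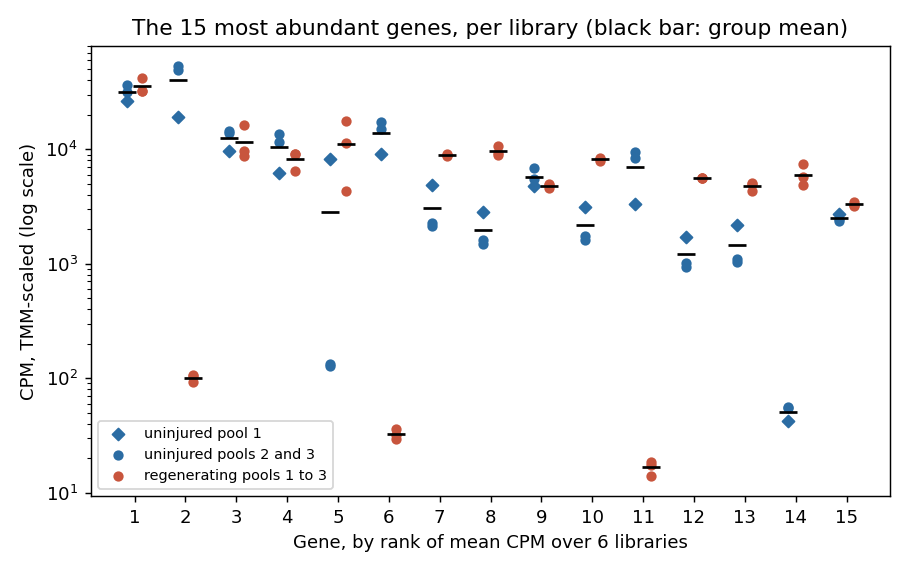
TMM-scaled CPM (y, log scale) of the 15 genes with the highest mean over the 6 libraries, ordered by rank (x), 1 point per library, with a black bar at the group mean; diamonds mark uninjured pool 1. The genes ranked 2, 6 and 11 are near 101, 32.4 and 16.7 CPM in regenerating pools, and in each of them uninjured pool 1 lies below pools 2 and 3.

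The fixed rule, which ranks genes by fitted change, took AMEX60DD033032 and AMEX60DD006022 among those that fell, genes of 460 and 403 bases. AMEX60DD033032 had 274, 840 and 618 reads in the uninjured libraries, or 16.1 ± 8.25 CPM (SD, n = 3), and AMEX60DD006022 had 234, 438 and 454, or 10.5 ± 4.13 CPM (SD, n = 3). Neither had a read in any regenerating library, which puts them at least 161-fold and at least 105-fold lower against the limit of 3 reads per library. These bounds do not show their falls to be larger than those of the genes ranked 2, 6 and 11. Their edgeR adjusted p values were 0.00157 and 0.000738.

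Among those that rose the rule took AMEX60DD030514 and AMEX60DD051700. AMEX60DD030514, 3433 bases long, had 1 read over the 3 uninjured libraries and 74, 452 and 1042 reads in the regenerating ones, or 16.7 ± 14.9 CPM (SD, n = 3). AMEX60DD051700, 769 bases long, also had 1 read over the uninjured libraries and 455, 634 and 312 in the regenerating ones, or 15.7 ± 5.70 CPM (SD, n = 3). The ratios of the groups were 1909 (95% exact interval 342 to 75464) and 1706 (306 to 67432), from counting error alone. The edgeR adjusted p values were 0.00217 and 0.000136. Chromosomal positions of these genes are not given in the sources used here.

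Changes were called more often in abundant genes. In the fifth of the tested genes with the highest mean level, from 23.3 CPM, 64.7% were called, and in the fifth with the lowest, up to 0.586 CPM, 20.6%. The median SE was 0.19 and 0.52 on the log2 scale. Of the 100 most abundant genes 52 rose, 26 fell and 22 were not called. Of those 26, 14 fell by at least 128-fold. Among the 1000 most abundant, 485 rose and 253 fell.

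Identifier type and length also went with the calls. Of the 11929 tested genes whose identifiers begin with AMEX60DDU, 20.2% were called, 1060 higher and 1346 lower, against 51.4% of the other 25915, of which 6669 rose and 6658 fell. The AMEX60DDU genes took 4.27% to 5.18% of the reads of a library. Their median SE was 0.41 on the log2 scale, against 0.31 for the other genes. The 2 types were not matched on abundance, so identifier type and abundance are not told apart here. In the fifth of genes with the greatest length, from 4869 bases, 1811 rose and 2582 fell, so that 41.2% of its calls were higher, against 49.1% of all calls. The share was also low in the fifth with the smallest length, up to 618 bases, at 42.3% (640 rose and 872 fell), and it was 57.0% in the middle class, 1469 to 2783 bases. The trend with length differed more within groups than between them. The median log2 deviation of the longest genes minus that of the shortest was -0.01 ± 0.087 in uninjured and -0.06 ± 0.11 in regenerating libraries (SD, n = 3 each; exact two-sided permutation p = 0.50).

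Uninjured pool 1 held levels between the groups for many changed genes. Its position was measured on a scale from 0, the mean of uninjured pools 2 and 3, to 1, the mean of the regenerating pools, over genes called without it, tested also with it, and with at least 10 CPM in the regenerating mean (risen genes) or in the mean of pools 2 and 3 (fallen genes). Over the 266 such genes that fell by at least 128-fold, the median position was 0.375 (10th to 90th percentile 0.0651 to 0.619). Over the 164 such genes that rose by at least 128-fold it was 0.000776 (-0.00281 to 0.0643). Without the minimum of 10 CPM, the medians were 0.358 (-0.0481 to 0.620) over 470 fallen genes and 0.00311 (-0.00244 to 0.441) over 358 risen genes. With it, over the 2463 genes that rose 2-fold to 8-fold it was 0.210 (-0.0226 to 0.635). The same measure of pool 2 from pool 3 had medians between -0.114 and 0.0188 in the classes with the minimum.

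**Figure D4:**
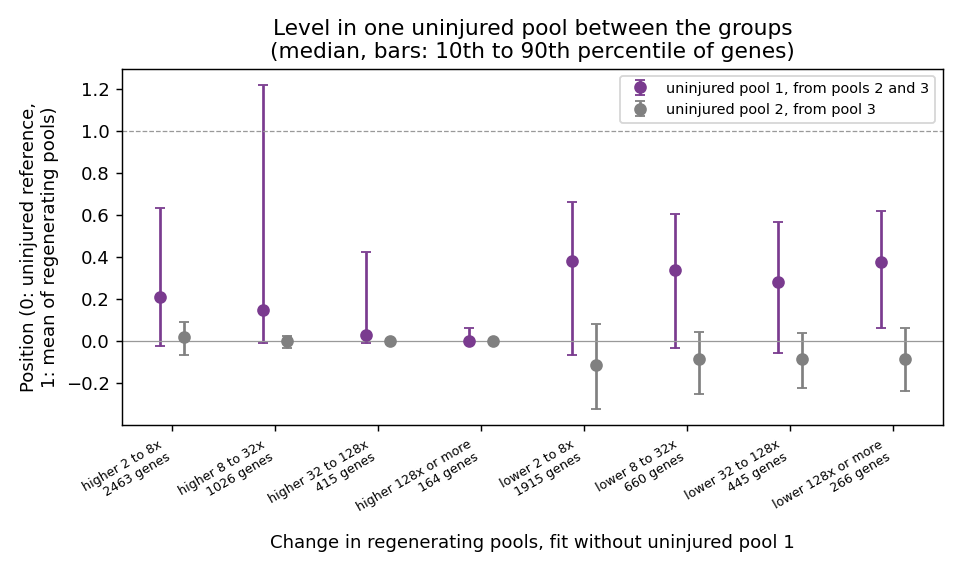
Position of uninjured pool 1 between the mean of uninjured pools 2 and 3 (0) and the mean of the regenerating pools (1) on the y axis, by direction and size of change in the fit without pool 1 (x), over genes with at least 10 CPM in the regenerating mean (risen) or in pools 2 and 3 (fallen), with the same measure for pool 2 from pool 3 in grey; points are medians over genes and bars the 10th to 90th percentiles. Pool 1 lies at 0.375 for these genes lowered at least 128-fold and at 0.000776 for those raised as much.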

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

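The transcript length test and its alternatives were chosen after the data were seen. A column outside the main measurement, the transcript length that Salmon weights by abundance within each gene, differed between the groups for 799 of 12691 genes with several transcript lengths and at least 100 reads on average (limma on log2 length, adjusted p under 0.05). Of these, 566 genes had shorter and 233 longer transcripts in the regenerating pools. The minimum of 100 reads is a mean over all 6 libraries, so a tested gene may have few or no reads in 1 group. Its length in that group then rests on little or no data. How many of the 799 genes this concerns was not counted. The mean log2 length over the tested genes was 11.81 to 11.83 in the 3 regenerating and 11.85 to 11.86 in the 3 uninjured libraries. With the pools paired by animal in a replicate block, 18 genes were shorter and 9 longer, while 2648 genes had an unadjusted p under 0.05, against 3191 without the block. The numbers shorter and longer were 88 and 61 without uninjured pool 2, 89 and 69 without uninjured pool 3, 396 and 145 without regenerating pool 1, 174 and 67 without regenerating pool 2, and 295 and 114 without regenerating pool 3. The count is as large in 1 of the 10 splits of the 6 libraries, the real one, and the highest other split gave 1 gene. Each other split holds libraries of both groups on both sides, so the group difference widens the spread within its sides. Few calls follow from that mixing, so these splits give no chance level. The 10 splits are too few for a share under 0.05.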

How the results depend on the processing

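The setting without the 100 most abundant genes, the transcript length tests, and the counts by size of change, abundance and length were chosen after the data were seen. No gene called by the edgeR test was called in the opposite direction in any setting, but the sign of 14 calls on log2(TPM + 0.5), 12 with length offsets and 13 in the series table turned without passing the threshold. The numbers of genes higher (7729) and lower (8004) stayed within 1.5 times under all 3 other scalings, both filters, DESeq2, limma-voom, limma on TPM, length offsets and the series table, at 5521 to 8432 and 6210 to 10447. They were 4410 and 5066 at an adjusted p under 0.01, and 3453 and 4150 for a change of more than 2-fold (edgeR glmTreat), where fewer genes can pass by construction. With pools paired by animal (replicate block) they were 6894 and 6964, 6557 and 6751 of them shared with the calls without it, and the block changed no call of the single genes described in the report. Leaving out 1 library gave 5219 to 10009 higher and 5804 to 9131 lower, the highest without uninjured pool 1. Smaller counts moved more. Genes higher by at least 8-fold went from 1927 to 3516 without uninjured pool 1, more than the 2942 then lower, and to 1030 on log2(TPM + 0.5), where 1714 instead of 2579 were lower by as much. In the fifth of genes with the greatest length, 1811 higher became 1141 on TPM, 1192 at the stricter p and 922 under glmTreat, and 2582 lower became 1719 in the series table and 1386 under glmTreat. Of the 100 most abundant genes, 28 instead of 52 rose under glmTreat. The cause was not tested. Genes with longer (233) and shorter (566) transcripts were 9 and 18 with the block, 150 and 462 at 1000 mean reads, and 61 to 266 and 88 to 524 without 1 library. The gene list tests were not run, since no symbol matched. Genes not called are not shown to be unchanged, and low levels are limited by depth to a floor of 0.0753 to 0.109 CPM.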

Other observations

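The counts over other splits and the settings of scaling, length offsets, TPM and series table were planned, but their use for the length classes, and all other tests of explanations in this part, were chosen after the result was seen. The spread within the uninjured group came largely with pool 1. Of 11550 genes with a mean of at least 10 CPM in the regenerating pools, 181 had more than a 4-fold range among the 3. Between any 2 of these pools, over genes with that mean in the 2 pools compared, the count was 76 to 126. Of 11383 genes with that mean in the uninjured pools, 481 had that range among the 3. Between uninjured pools 2 and 3, over genes with that mean in these 2, the count was 16, fewer than between any 2 regenerating pools. The gene AMEX60DD030514 was 1 of the variable ones, with 74 reads in regenerating pool 1 and 1042 in pool 3.

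A set of genes was shared between uninjured pool 1 and the regenerating retina. In pool 1, 683 genes with at least 10 CPM were over 4-fold above the mean of pools 2 and 3, against 6 genes in pool 2 over pool 3 and 16 in pool 3 over pool 2. These 683 genes took 5.89% of the reads of pool 1 (95% Wilson interval 5.89% to 5.90%), 0.359% (0.357% to 0.361%) and 0.418% (0.416% to 0.421%) in pools 2 and 3, and 7.10% ± 1.01 in the regenerating pools (SD, n = 3). Their level in pool 1 was at or above the regenerating mean for 391 of them, with a median ratio of 1.21. Of these genes 94 were called higher in the main comparison, and 547 more were called higher when pool 1 was left out, 93.9% of the 683 in all. Of all genes tested both with and without pool 1, 25.7% were called higher without it. Part of the share of the 683 may come from the use of pools 2 and 3 on both sides. In libraries simulated without any change, 67 genes were raised in the same way. Of these, 20.9% were higher at an unadjusted p under 0.05 (edgeR), against 95.5% of the 683. At the adjusted p 0% were called, but with no gene changed few calls can pass it, so that 0% is no measure of this effect.

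The first pattern is the place of uninjured pool 1. RNA of regenerating retinas mixed into that pool would add at least its share to every risen gene, but the 164 genes that rose at least 128-fold with at least 10 CPM had a median position of 0.000776 (0.00311 over 358 without that minimum, where the 90th percentile was 0.441), against 0.375 for genes that fell as much, which argues against it. The log2 ratio of pool 1 to pools 2 and 3 differed by 0.000392 between the longest and shortest genes, so no steady trend with length showed. A trend that moves both ends alike would be missed, and RNA integrity itself was not tested. Dilution by a single factor was not decided. Over the genes lost in regeneration, the log2 ratio in pool 1 spread 3.26 times as widely as that of pool 2 to pool 3. Those 2 pools were the most alike within a group. They differed by 13.5 times the variance of read sampling, against 29.6 to 70.2 times between regenerating pools. Ordinary spread between pools could therefore add to a single factor. Also open is that pool 1 may hold transcripts of other cells that the regenerating pools hold too. Of the genes over 4-fold above pool 2 in pool 1, 94.4% were over 2-fold above pool 3 in the regenerating mean. Of other genes matched on level, 26.2% were. With pools 2 and 3 exchanged, the shares were 96.5% and 25.7%. A difference between the animals of the pools stays open as well, although regenerating pool 1, from the same animals, had the lowest share of the reads in the 683 genes (5.98% against 7.95% and 7.37%) and a deviation from its group correlated at -0.01 with that of uninjured pool 1.

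The second pattern is the excess of losses among the longest genes, which the shortest genes shared (42.3% of calls higher). Whether the authors' length model caused it was not decided. The share of calls that were higher in the longest genes minus that in all genes was taken as a gap. It was -6.68 percentage points with effective length offsets, against -7.90 without them. The offsets hold only differences in a gene's effective length between libraries. A length that a gene has in all libraries alike cancels from its fold change, so the offsets could move the gap little. The series table, which carries no weight for length, gave -6.82, while limma on log2(TPM + 0.5), which also changes the filter, the scaling and the test, gave -2.65, in a range over all settings of -9.10 to -2.65. A trend with length between single libraries was not decided, since the group means differed by 0.247 times the largest range within a group and the measure sets the longest against the shortest genes, which lean the same way. The regrowth itself stays open as a cause, untested.

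The third pattern is the balance of genes higher and lower. Whether a few genes taking most of the counts caused the rises was not decided. Under library totals 6263 genes were called higher without the 100 most abundant genes and 6256 with them. The median fold change moved from that of the main fit by -0.19 without and -0.16 with them, on the log2 scale. Leaving them out thus hardly changed the scaling, and all other changed genes stayed in. The number of rises did not rest on these 100 genes. The 15733 calls were matched in 1 of the 10 splits of the 6 libraries, the real one. The highest other split gave 0 calls (edgeR), and the 9 others had 167 to 1161 genes at an unadjusted p under 0.05. Each of the others holds libraries of both groups on both sides, so the group difference widens the spread within its sides. Few calls follow from that mixing, so these splits give no chance level for the 15733 calls. The 10 splits are too few for a share under 0.05. Of the others, 3 parted all 3 pairs of pools, as the real one does, and gave 0 calls, but their sides mix both groups too.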
